A study of Mus musculus with 2 samples.

How the data were processed

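Small RNA from the intestine of mouse embryos of the B6NCrl strain at 14.5 days of development was sequenced in 2 libraries, which the labels describe as biological replicates 1 and 2. Each library came from total RNA with inserts under 30 bases, per the labels. The labels describe each sample as the intestine of a single pup and also give the sex as pooled male and female; the values cannot settle which holds. The tissue was collected on day 17 of the month for replicate 1 and day 15 for replicate 2, so that collection day and replicate cannot be separated.

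The deposited tables hold whole-number counts of reads per gene, one table per library, with both strands together, the gene's strand and the opposite strand in separate columns. This reading of the columns rests on the values. The first column is the sum of the other 2 for every gene, and the abundant microRNA genes hold nearly all of their counts in the second. Per the files that accompany the tables, the reads were aligned to mm10 and assigned to genes of GENCODE release M4. The aligner, its settings, the adapter trimming and the counting program were not given in the sources used here. Reads that did not align, aligned to several places, met no gene or met more than one gene stand in rows of their own and entered neither totals nor tests. In replicates 1 and 2 respectively, unaligned reads made up 12.4% and 13.8% of the reads in the table, reads with several alignments 26.5% and 26.6%, and reads on no gene on either strand 2.20% and 2.10%. No read was recorded as ambiguous. No molecular identifiers are recorded in the tables, so PCR copies count as reads.

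Counts on the gene's strand were the measurement. They were divided by the total of such counts over the 1973 rows that name a gene and scaled to a library total of 1000000 (CPM). These totals were 15090126 in replicate 1 and 3903472 in replicate 2, so that replicate 1 was 3.87 times deeper. A count of 0 allows a level of up to 0.199 CPM in replicate 1 and 0.769 CPM in replicate 2, taking 3 counts of the total as the limit. Shares of a single library carry Wilson 95% intervals. For the summed share of a gene list the interval reached at most 0.0190 percentage points either way in replicate 1 and 0.0354 in replicate 2. All intervals and limits cover counting error only. They leave out differences between animals and in ligation, PCR and dissection. Ligation and PCR favour some small RNA sequences over others, so levels of different microRNAs are compared here as counts, not as molecules.

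Gene symbols, positions and hairpin sequences came from GENCODE release M21, which uses GRCm38, the assembly also called mm10. Of the 1973 gene identifiers, 1894 were found in it, 1815 of them with the same version. The other 79 had at most 2 counts each. Coordinates are those of M21, and for a gene whose version differs they may not be the interval used for counting. A gene was called detected with at least 10 counts in both libraries. A gene was said to share sequence when its annotated hairpin held an identical stretch of 20 bases, in either orientation, with a microRNA hairpin at another place in the genome. Copies on the opposite strand of the same place were left out of this definition after the counts had been seen. Genomic clusters are genes on one strand within 10 kb of the next, with at least 3 detected members.

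The design holds 1 group, so no condition was compared with another and no p-value for a condition exists. The main measures were the abundance profile, the summed share of 27 gene lists, 11 ratios between lists, the agreement of the replicates and the counts on the opposite strand. Agreement was measured across detected genes as Pearson's r of log2(CPM + 1), Spearman's rho, the median absolute log2 difference and the common dispersion of edgeR, given as the biological coefficient of variation. Each gene's 2 counts were also tested against the ratio of the library totals with a two-sided exact binomial test, with Benjamini-Hochberg adjustment over the detected genes at a threshold of 0.05. That test compares these 2 libraries and nothing beyond them. Differences are written as log2 of replicate 2 over replicate 1. The median difference of a list with at least 3 detected members was placed among 10000 random lists of the same size, drawn from 10 bins of mean CPM. Random lists of single genes ignore that neighbours move together, so lists at 2 or more loci were also placed with 1 median per locus, a locus being genes on one strand within 10 kb of the next. A ratio between lists was called larger than the spread when it had one sign in both libraries and its mean exceeded the 95th percentile of the absolute log2 differences between libraries. That spread is one of single genes and not of sums over lists, so each ratio was also set against its own difference between the libraries, a measure added after the data had been seen.

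The lists, the ratios, the thresholds and the naming rule were fixed before the data were examined. The rule named the 20 genes with the highest mean CPM and up to 4 members of each list with the highest mean CPM. It also named the 10 genes with the largest difference between libraries among those with a mean of at least 100 CPM, and up to 3 genes with the most counts on the opposite strand. Together these are 105 genes, of which the text gives a part. Genes named after their values were seen are Mir802 and the low-count genes over 2-fold apart, the abundant genes outside the lists and the rule, and further members of lists, clusters and copy families. The last are Mir196a-2, Mir200a, Mir19b-1, Mir19b-2, Mir92-1, Mir292, Mir293, Mir3070a, Mir24-2, Mirlet7a-1, Mirlet7a-2 and the neuronal and striated muscle genes named as sharing sequence. Gm24111 and genes annotated opposite a counted gene were also named then. The list table held 252 symbols including spelling variants, of which 205 matched a row.

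The alternatives were the column of both strands together, a minimum of 1 or 50 counts, edgeR's TMM scaling, DESeq2's size factors, a total without Mir143, a pseudocount of 10 CPM, leaving out genes that share sequence and leaving out each replicate. Thinning replicate 1 to the total of replicate 2, placing lists by locus, leaving out Mir802 and all settings for the Mir802 difference were added after the data had been seen. The exact test, the dispersion, the placement of lists and both permutation tests were tested on simulated data; the ratios between lists were not. For the comparison of the 2 libraries' counts, run on 363 genes with 200 changed, the exact test called 76.1% of genes changed 1.5-fold, 94.0% of those changed 2-fold, 98.5% of those changed 4-fold and 3.7% of unchanged genes. On 363 genes simulated with a coefficient of 0.05, 0.1 or 0.2 the estimate was 0.0519, 0.0942 and 0.203. Of 20 random lists with no shift all 20 lay within the central 95% of random lists, and of 20 lists shifted by 0.5 log2 none did. Among 363 genes simulated in groups of 3 neighbours, 17 of 20 lists of 3 whole groups with no shift lay within it by gene and 18 by locus, and 1 and 3 of 20 with that shift. Each of these simulations used lists of one size and one spread of differences between genes. Smaller shifts were not simulated, so how often those would be called is unknown. The permutation test on shared sequence, run on 205 genes, gave p under 0.05 in 2 of 20 simulations with no effect and 19 of 20 with one. That on clusters, run on 108 genes, did so in 1 of 20 and 19 of 20. The software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. DESeq2 served for size factors alone.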

Results

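MicroRNA levels were measured in the intestine of mouse embryos at 14.5 days of development, in 2 biological replicates of a single group. The labels name no second condition, and the series serves as a profile of this tissue at this age. MicroRNAs are short RNAs, cut from hairpin precursors, that repress messenger RNAs. Replicate 1 held 26361292 reads in its table and replicate 2 held 7003185. Of these, 57.2% and 55.7% were assigned to a microRNA gene on its own strand. Values below are CPM, such counts scaled to a library total of 1000000, as mean ± SD of the 2 libraries (n = 2) unless one library is named.

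The embryonic intestine was dominated by a small set of microRNAs, led by Mir143, a microRNA known from smooth muscle. Mir143 (ENSMUSG00000065445.2; GRCm38 chromosome 18, 61649196 to 61649258, minus strand, outside other annotated genes on its strand) reached 157004 ± 15498 CPM. It took 16.8% of the counts in replicate 1 (95% interval 16.78 to 16.82%) and 14.6% in replicate 2 (14.57 to 14.64%). Mir10a (ENSMUSG00000065519.1; chromosome 11, 96317165 to 96317274) of the Hoxb cluster followed at 62116 ± 4588 CPM, and Mir335, in an intron of the imprinted gene Mest, at 52828 ± 2999 CPM. Mirlet7g (37548 ± 2206 CPM), Mir10b (35182 ± 5748 CPM), Mir26b (32343 ± 453 CPM) and Mir17 (30357 ± 246 CPM) came next.

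The other genes among the 20 most abundant were Mir99a (28946 ± 704 CPM), Mir130a (28698 ± 169 CPM), Mir23b (24075 ± 2164 CPM), Mir126a (23826 ± 493 CPM), Mirlet7i (22671 ± 945 CPM), Mir30e (22223 ± 1663 CPM), Mir21a (17954 ± 2032 CPM), Mir99b, Mir429, Mir322, Mir20a, Mir200c and Mir23a (11066 ± 609 CPM). The same 20 genes led both libraries, and 18 of them belonged to a list fixed beforehand. The 10 most abundant genes held 48.9 ± 1.86% of the counts, 11 genes held 50% and 65 genes held 90%. In all, 363 of the 1973 genes had at least 10 counts in both libraries and 1205 had none in either. A mean of at least 100 CPM was reached by 195 genes and of at least 1000 CPM by 102.

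**Figure D1:**
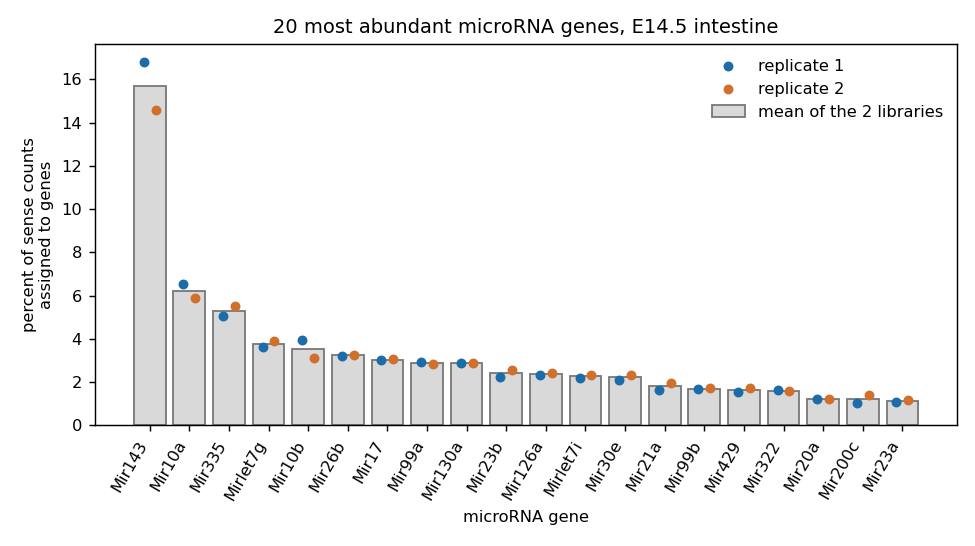
Share of sense counts (percent, vertical axis) for the 20 most abundant microRNA genes (horizontal axis), with bars for the mean of the 2 libraries and points for replicate 1 and replicate 2. Mir143 stands apart at 16.8% in replicate 1 and 14.6% in replicate 2, and Mir10a follows at 6.54% and 5.89%.

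MicroRNAs known from smooth muscle took a far larger share of the counts than those known from intestinal epithelium. The smooth muscle pair Mir143 and Mir145a made up 16.1 ± 1.55% of the counts, while the intestinal epithelial microRNAs Mir192, Mir194-1, Mir194-2 and Mir215 made up 1.02 ± 0.168%. The first sum exceeded the second 15.9-fold, with log2 ratios of 4.26 and 3.72 in replicates 1 and 2, a gap of 0.54 between the libraries. It compares counts of different microRNAs and measures no share of cells. Nearly all of this was Mir143, because Mir145a, which lies beside it on chromosome 18 (61647825 to 61647894), reached 3582 ± 21.6 CPM. Within the epithelial group Mir215 stood at 3443 ± 722 CPM, Mir192 at 3384 ± 228 CPM and Mir194-2 at 2565 ± 511 CPM. Mir194-1 and Mir194-2 share sequence, so their levels, separate and summed, and the share of the list are uncertain. No smooth muscle gene shares sequence. Reads left out for several alignments would therefore lower the epithelial sum alone, and the 15.9-fold ratio may be too high. Without Mir194-1 and Mir194-2 the log2 ratio was 4.56, against a mean of 3.99 with them. Leaving them out lowers the epithelial sum further, so it does not test this.

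The miR-200 family, which maintains epithelial identity, was well represented at 3.90 ± 0.556% of the counts. Mir429 had 16430 ± 1398 CPM, Mir200c 12141 ± 2778 CPM, Mir200b 7212 ± 785 CPM and Mir141 2087 ± 432 CPM. The family exceeded the mesenchymal list of miR-199 and miR-214 genes (1.05 ± 0.106%) 3.72-fold (log2 ratio 1.89 ± 0.06), far more than the ratio differed between the libraries. Mir214 (9835 ± 1081 CPM) carried the mesenchymal list, whose Mir199b, Mir199a-2 and Mir199a-1 share sequence and had 498 ± 22.0, 114 ± 2.85 and 9.03 ± 1.72 CPM. As no miR-200 gene shares sequence, reads left out for several alignments would lower the mesenchymal sum alone, and the ratio may be too high. The endothelial gene Mir126a, in an exon of Egfl7, gave 2.38 ± 0.0493% of the counts.

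MicroRNAs of the Hox clusters formed the second largest list, at 10.7 ± 1.21%. The Hox genes lay down position along the gut, and their microRNAs lie in the same clusters, several of them within annotated Hox genes. Besides Mir10a and Mir10b (an intron of Hoxd3 and Hoxd4 on chromosome 2, 74726070 to 74726137), Mir196b (an exon of Hoxa9) had 8324 ± 1583 CPM and Mir615 (an intron of Hoxc5) 1522 ± 121 CPM. Imprinted loci were also prominent. The Dlk1-Dio3 region on chromosome 12 gave 7.12 ± 0.169% of the counts from 43 detected genes of 49 measured, led by Mir127 (9772 ± 226 CPM), Mir411 (8428 ± 581 CPM), Mir487b (8221 ± 78.5 CPM) and Mir541 (6088 ± 133 CPM). Opposite-strand counts of 4 genes there, at the places of Mir409, Mir376a, Mir299a and Mir380, amounted to a further 1.35 ± 0.0301% of the total and did not enter that sum. The other imprinted loci gave 6.28 ± 0.372%, mostly Mir335, with Mir296 at 4441 ± 284 CPM, Mir298 at 3298 ± 343 CPM and Mir483, in an intron of Igf2, at 2063 ± 105 CPM.

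**Figure D2:**
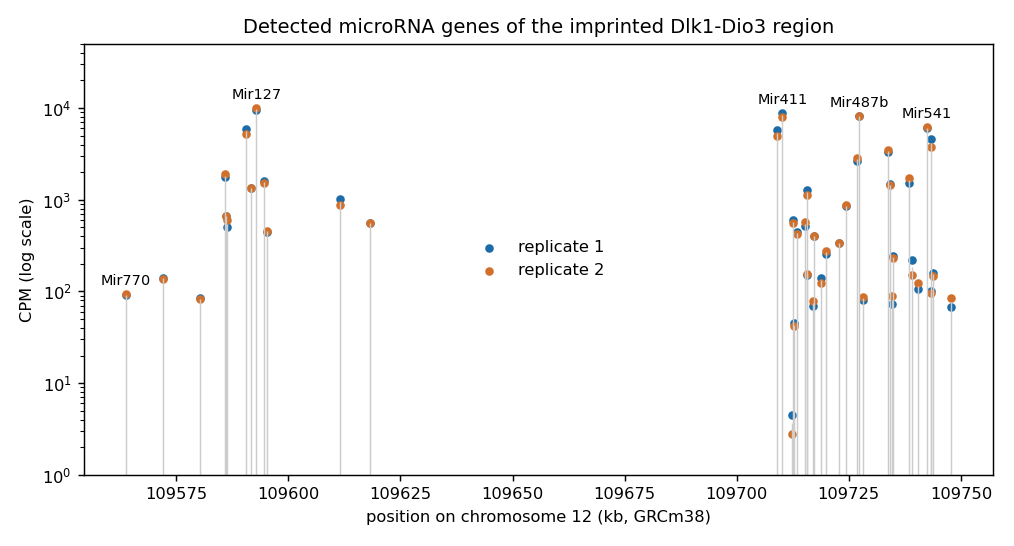
Levels (CPM, log scale, vertical axis) of the detected microRNA genes of the Dlk1-Dio3 region against their position on chromosome 12 (kb, GRCm38, horizontal axis), with points for replicate 1 and replicate 2 and grey lines up to the mean. Neighbouring genes differ widely, with Mir127 at 9772 CPM and Mir411 at 8428 CPM among the most abundant.

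Let-7 microRNAs, associated with differentiation, and the proliferation-associated miR-17-92 cluster with its paralogues had similar summed counts. Let-7 gave 7.58 ± 0.451% and miR-17-92 with paralogues 7.01 ± 0.0515% of the counts, a 1.08-fold difference (log2 ratio 0.11 ± 0.10) that did not exceed the gap of 0.14 between the libraries. Of the let-7 genes 5 of 10 share sequence, as do 4 of the 15 others, so both sums are uncertain; without such genes the log2 ratio was 0.16. Counts opposite Gm25927 and Gm24111, where Mirlet7e and Mirlet7f-1 are annotated, amounted to 0.456 ± 0.0194% of the total and did not enter the let-7 sum. Mirlet7g and Mirlet7i led the first, ahead of Mirlet7d (8161 ± 659 CPM) and Mir98 (4505 ± 334 CPM). Mir17 and Mir20a (12149 ± 157 CPM) led the second, with Mir93 (8712 ± 135 CPM) and Mir106b (7035 ± 643 CPM) of the Mcm7 locus. The pluripotency clusters miR-290 and miR-302 were low, at 0.0310 ± 0.000174%, and let-7 exceeded them 244-fold (log2 ratio 7.93 ± 0.08). Of the 12 pluripotency genes measured, 4 share sequence, and without sharing genes in either list the log2 ratio was 9.21. Mir302d, for example, had 101 ± 8.12 CPM.

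Among the broadly expressed families, the clusters of Mir99a, Mir99b and Mir100 gave 5.98 ± 0.112%, miR-23/24/27 3.79 ± 0.252% (all 5 of its genes share sequence, Mir23b and Mir23a included), miR-30 3.43 ± 0.257%, miR-26 3.24 ± 0.0459%, the X-linked Mir322 cluster 2.19 ± 0.0173%, miR-181 1.37 ± 0.0206% and miR-15/16 0.754 ± 0.0372%. The miR-29 family had few counts, 0.0127 ± 0.000947%, with Mir29c at 74.6 ± 9.39 CPM and Mir29a at 51.0 ± 0.401 CPM. As 3 of its 4 genes share sequence and reads with several alignments were assigned to no gene, its level is uncertain; without those genes the share was 0.00556%. The miR-34 and miR-449 family of multiciliated cells gave 0.0930 ± 0.000791%, chiefly from Mir34c (707 ± 18.9 CPM).

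Markers of other cell types were mostly low. Neuronal microRNAs gave 0.0714 ± 0.00597%, a log2 ratio of -3.82 ± 0.12 to intestinal epithelium, and were led by Mir132 (239 ± 39.8 CPM). Of the 14 neuronal genes 11 share sequence, among them Mir124a-1, Mir124a-2, Mir124a-3 and Mir9-2 with at most 1 count, so the low sum may reflect unassigned reads. Without such genes the share was 0.0327%. The list also leaves out Mir137, known from neural tissue. That gene alone had 2042 and 2316 CPM in replicates 1 and 2, against 672 and 757 CPM for the whole list. The liver gene Mir122 had 45.4 ± 7.89 CPM, and intestinal epithelium exceeded it 224-fold (log2 ratio 7.81 ± 0.01). Striated muscle genes gave 0.00347 ± 9.3e-05%, which smooth muscle exceeded 4614-fold (log2 ratio 12.17 ± 0.10). Here 5 of 9 genes share sequence, Mir1a-1, Mir133a-1 and Mir133a-2 with 5, 0 and 1 counts in replicate 1 among them, so that ratio may be too high. Erythroid genes gave 0.0334 ± 0.0106%, with Mir451a at 303 ± 101 CPM, and endothelial Mir126a exceeded them 73.3-fold (log2 ratio 6.20 ± 0.44). Leukocyte genes gave 0.0502 ± 0.00767%, led by Mir223 (426 ± 66.0 CPM), and 0.109% with both strands counted. The erythroid to leukocyte log2 ratio was -0.79 in replicate 1 and -0.45 in replicate 2. Its mean was -1.77 with both strands counted, where reads on the opposite strand of Mir142b enter the leukocyte sum.

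Genes known from pancreas and from stratified epithelium reached levels close to those of the intestinal epithelial list. The stratified list gave 0.589 ± 0.0439%, with Mir203 at 4147 ± 164 CPM, Mir205 at 1067 ± 203 CPM and Mir31 at 674 ± 71.7 CPM. Intestinal epithelium exceeded it 1.72-fold (log2 ratio 0.69 and 0.87 in replicates 1 and 2). Without genes that share sequence the log2 ratio was 0.21. That setting removes Mir194-1 and Mir194-2 and no stratified gene. Reads left out for several alignments would lower the intestinal sum alone, so these 2 lists may lie further apart than counted. The pancreatic list gave 0.655 ± 0.337%, nearly all Mir375 (5778 ± 3226 CPM), a microRNA of endocrine cells that the gut epithelium also expresses. Intestinal epithelium exceeded it 1.65-fold, with log2 ratios of 1.11 in replicate 1 and 0.35 in replicate 2, whose gap of 0.76 exceeded the mean of 0.73. Without genes that share sequence the mean was 0.19. Mir375 does not share sequence, but Mir7-1 and Mir7-2 do, so reads may be missing from both of these sums. Of the 11 ratios, 9 exceeded their own gap between the libraries and 8 the planned spread of 0.73, which is that of single genes. No test of the ratios was run; an exact test over 2 libraries cannot reach 0.05.

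**Figure D3:**
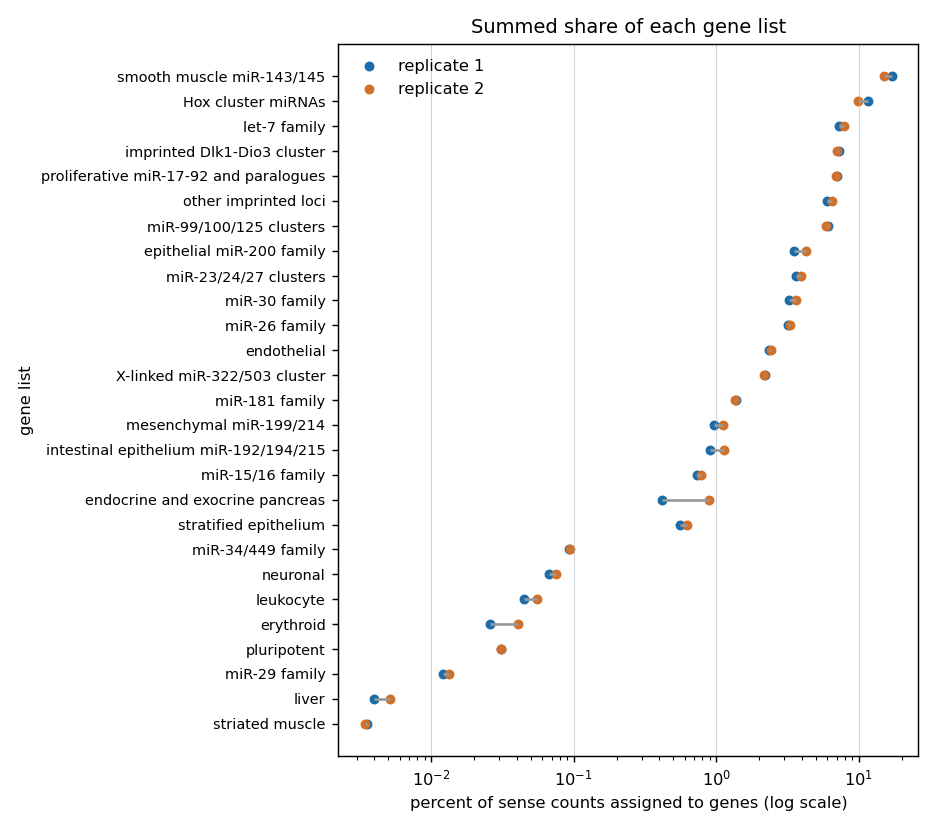
Summed share of sense counts (percent, log scale, horizontal axis) of each gene list (vertical axis), with points for replicate 1 and replicate 2 joined by a line. Smooth muscle leads at 16.1% on average, and the pancreatic list has the widest gap, from 0.417% in replicate 1 to 0.894% in replicate 2.

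MicroRNAs lying together in the genome differed widely in level. In 15 clusters with 97 detected genes, the most and least abundant members were between 2.17-fold (Mir293 over Mir292) and 3443-fold apart (Mir127 over Mir3070a). Mir3070a shares sequence with another locus, so its level and the 3443-fold range are uncertain. In the miR-17-92 cluster (chromosome 14, 115043671 to 115044506, the Mir17hg transcript) Mir17 held 59.1% of the counts and exceeded Mir19b-1 1052-fold. Mir19b-1 shares sequence with Mir19b-2, so its level is uncertain. On the X chromosome (53047997 to 53054349) Mir322 (16019 ± 436 CPM) held 73.2% of its cluster, and on chromosome 4 (156053905 to 156055750) Mir429 held 66.4% of the cluster it forms with Mir200a and Mir200b. The larger Dlk1-Dio3 segment (chromosome 12, 109709060 to 109747960) had 30 detected genes, of which Mir411 held 17.7%.

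The 2 libraries had closely similar profiles, apart from Mir375 and Mir802. Mir375 (ENSMUSG00000065616.2; chromosome 1, 74900658 to 74900721) had 3497 CPM in replicate 1 and 8059 CPM in replicate 2, a 2.30-fold difference (log2 1.20, 95% counting interval 1.18 to 1.22). Mir802 (ENSMUSG00000076457.1; chromosome 16, 93369720 to 93369816), a gene outside the naming rule and chosen after its values were seen, had 24 counts in replicate 1 and 533 in the shallower replicate 2. These are 1.59 and 137 CPM, an 85.9-fold difference (interval 57.1 to 135-fold). No other gene with a mean of at least 50 CPM differed over 2-fold.

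Across the 363 detected genes, Pearson's r was 0.994 and Spearman's rho 0.993; genes are not independent replicates. The median absolute log2 difference was 0.15, or 1.11-fold, and 95% of genes lay within 1.65-fold. The biological coefficient of variation was 0.170, and 0.108 without Mir802. The 8 genes over 2-fold apart were all higher in replicate 2, and 6 of them had under 50 counts in a library. Besides Mir375 and Mir802 they were Mir7-2 (11.3 and 40.2 CPM, adjusted p = 1.61e-27 by the exact binomial test), Mir216b (13 and 12 counts, adjusted p = 0.00572 by the exact test), Mir5619, Mir7213, Mir3474 and Mir7026. The last 5 and Mir802 were named after their values were seen, and Mir3474 and Mir7026 did not pass the test. As replicate 1 was 3.87 times deeper, the minimum of 10 counts in both libraries favours low genes that are higher in replicate 2, so their direction says little. With replicate 1 thinned to equal depth and a minimum of 20 counts summed over both, 5 genes were over 2-fold higher and 1 lower.

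**Figure D4:**
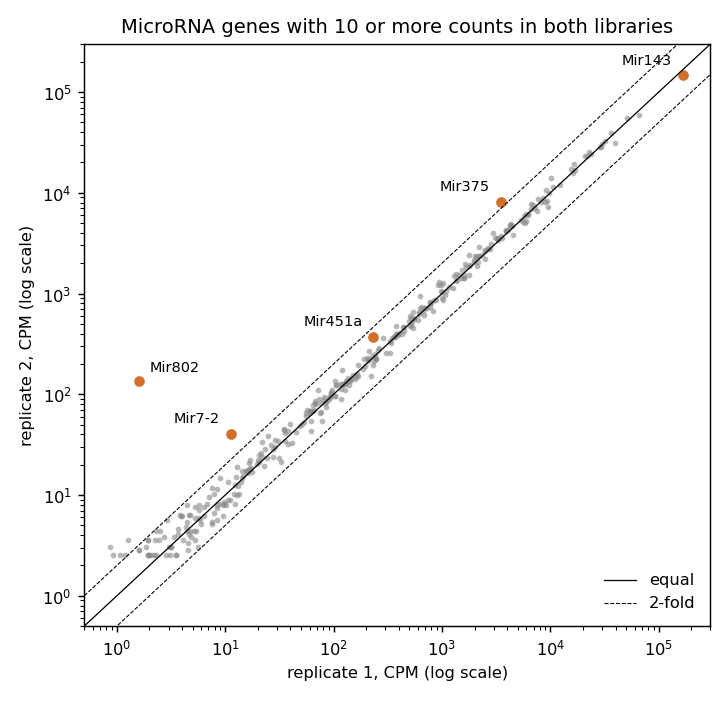
Level in replicate 2 (CPM, log scale, vertical axis) against replicate 1 (CPM, log scale, horizontal axis) for the 363 detected genes, with lines for equal levels and 2-fold differences. Mir802 lies far above the lines (1.59 and 137 CPM), and Mir375 is the most abundant gene outside them (3497 and 8059 CPM).

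Intestinal epithelial and pancreatic microRNAs were higher in replicate 2 as groups, and Hox cluster microRNAs lower. Erythroid genes were higher too, chiefly through Mir451a. All 4 intestinal epithelial genes were higher and passed the exact test (4 adjusted over the list alone), with a median log2 difference of 0.42 at percentile 99.9 of matched random lists. The 5 miR-200 genes did likewise (5 adjusted over the list alone, median 0.32, percentile 99.9). With 1 value per locus, however, the miR-200 list lay within the central 95% (percentile 92.3). The largest differences in both lists were Mir194-1 (0.59), Mir200c (0.47), Mir215 (0.43), Mir141 (0.43) and Mir194-2 (0.41). Mir194-1 and Mir194-2, 1 at each of 2 loci, share sequence. Thus 2 of the 4 intestinal epithelial values are uncertain, by gene and by locus. The others were Mir215 and Mir192 (0.14), and no percentile was computed without the sharing pair. Of 7 pancreatic genes measured, 6 were detected, and all 6 were higher and passed (6 adjusted over the list alone; median 1.02, percentile 100). Of these, Mir7-1 and Mir7-2 share sequence, so their values are uncertain. Mir216b had 13 counts in replicate 1 and 12 in replicate 2. The count minimum favours such low genes when they are higher in replicate 2, so its direction says little. The percentile was not computed without these genes. All 3 erythroid genes were higher (median 0.69, percentile 99.8), but 1 of them, Mir451a (0.69), passed over all detected genes and 3 adjusted over the list alone. The counting intervals of Mir144 (-0.009 to 0.62) and Mir486 (-0.002 to 1.44) included no change.

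All 6 Hox cluster genes were lower in replicate 2, 5 of them past the test over all genes and 5 adjusted over the list alone (median -0.35, percentile 0.01). Mir196b (-0.39), Mir196a-2 (-0.37), which shares sequence, and Mir10b (-0.33) differed more than Mir615 (-0.16) and Mir10a (-0.15). All 10 let-7 genes were higher, 8 of them past either test, by a small median of 0.19 (percentile 98.1). These 6 lists, of 23 with at least 3 detected members, lay outside the central 95% of random lists when genes were drawn singly. Neighbouring genes moved together, however, and the 4 intestinal epithelial genes lie at 2 loci, the 5 miR-200 genes at 2 and the 3 erythroid genes at 2. With 1 value per locus, chosen after the data had been seen, 22 lists could be placed. The percentiles were 99.4 for intestinal epithelium, 98.7 for erythroid genes, 100 for pancreas and 0 for Hox genes. The miR-200 list (92.3) and let-7 (96.6) then lay within the central 95%. The other genes with the largest differences were Mir496a (-0.53), Mir7-1 (0.52), which shares sequence with Mir7-2, and Mir148a (0.46).

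The remaining 17 lists stayed within that range. Dlk1-Dio3 genes were evenly divided, 21 higher and 22 lower. Of the miR-23/24/27 genes 2 were higher and 3 lower, all 5 past the test. The 3 leukocyte genes were higher, 2 past the test, as were the 3 stratified genes, 3 past the test. In all, 159 genes differed beyond counting error, 108 higher and 51 lower in replicate 2. Of these 143 differed by under 1.5-fold. The split depended on the scaling, with 68 higher and 80 lower under TMM, 72 and 77 under size factors, and 87 and 67 with Mir143 left out of the total. A chi-square of 164 per degree of freedom (362 degrees) showed that the tables were not one library deposited in duplicate. Collection day differed between the replicates, so these differences compare 2 libraries and their days together.

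Many microRNA genes that share sequence with another locus had low counts, with exceptions. Of the 363 detected genes, 85 held a stretch of 20 bases found at another microRNA locus. Within families, Mir26b had 32343 CPM against 58.4 ± 3.70 CPM for Mir26a-2 and 15.7 ± 2.06 CPM for Mir26a-1, which share sequence. Mirlet7a-1 and Mirlet7a-2 had 119 ± 23.0 and 114 ± 13.2 CPM against 37548 CPM for Mirlet7g. In contrast, Mir23b (24075 CPM), Mir23a (11066 CPM), Mir411 (8428 CPM), Mir487b (8221 CPM) and Mir92-1 (3450 CPM) share sequence and were abundant. Of the reads in the tables, 26.5% in replicate 1 and 26.6% in replicate 2 had several alignments and were assigned to no gene, so the levels of such copies are uncertain.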

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

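The strand check over abundant genes was chosen only after the opposite-strand counts had been seen; the other tests in this part were set beforehand, but the definition of shared sequence was narrowed after the counts had been seen. With a single group, no explanation resting on a difference between conditions was tested.

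A column that the profile leaves out held a clear signal. Reads on the strand opposite to the counted gene made up 2.89% of the counts on genes in replicate 1 and 3.10% in replicate 2. Most lay in a few predicted genes with no count on their own strand. Gm25301 (chromosome 18, 61397813 to 61397925) had 124721 such counts in replicate 1 and 36122 in replicate 2. Gm24321 (chromosome 12, 109743158 to 109743237) had 85595 and 24955, and Gm25927 (chromosome 17, 17830343 to 17830459) had 65654 and 17951. In all, 10 genes with more opposite-strand than own-strand counts held 99.7% of these reads in each library.

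Reads put on the wrong strand in library preparation would appear in every abundant gene. The share on the opposite strand was 0% at the median of the 50 genes with the most counts, which argues against this. Another annotated gene on the opposite strand remains a candidate source, since 99.9% of these counts lay where a gene is annotated there. Gm25301 lies opposite Mir378a, Gm24321 opposite Mir409 and Gm25927 opposite Mirlet7e. Read that way, the counts may be those of Mir378a, Mir409, Mirlet7e and, at Mir142b with 8096 and 2730 counts, of Mir142, a leukocyte microRNA.

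Reads with several alignments, assigned to no gene, made up 26.5% of the reads in replicate 1 and 26.6% in replicate 2. If these reads come from microRNAs with several identical copies, such copies should have low counts. Among members of the 19 lists with a summed level of at least 1000 CPM, the 41 genes that share sequence had a median of 149 CPM and the 111 others 1345 CPM. The log2 ratio was -3.16, and the two-sided permutation p of 0.0001 within lists was the smallest that 10000 permutations can give. Loss of such reads is consistent with the low levels of Mir26a-1, Mirlet7a-1 and Mir24-2. Not every sharing gene had few counts, as Mir23b had 24075 CPM, though how many of its reads were left out is unknown. Truly low transcription of single copies cannot be excluded by counts alone.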

How the results depend on the processing

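The settings without Mir802, all settings of the Mir802 difference, both thinnings of replicate 1, the percentiles by locus and the own gap of each ratio were chosen only after the results were seen; the others were planned. No paired analysis was possible because there is a single group. No ratio between lists changed sign under the alternatives run on it. Of the differences of named genes, only the 10 largest chosen by the naming rule were run, and none changed sign. The median differences of the miR-17-92, Mir322 and Mir99a lists, 0.03, 0.03 and 0.01, became -0.04, -0.04 and -0.06 under TMM. Scaling by TMM, size factors or a total without Mir143 lowered every log2 difference by one constant, at most 0.07. Larger differences, those of the 10 genes run included, could not change sign under it. Smaller positive ones, such as those of Mir17 (0.02) and Mir26b (0.03), became negative under TMM. The number of genes beyond counting error stayed within 1.5 times of 159 under all 8 alternatives, as did the 11 genes holding 50% of counts under all 5.

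List shares moved by more than the SD between replicates in 25 of 27 lists with Mir143 left out of the total, where the smooth muscle share was 0.425%, and in 18 without genes that share sequence. In the latter case miR-23/24/27 went from 3.79% to 0%, neuronal genes from 0.0714% to 0.0327%, pluripotency genes from 0.0310% to 0.0137% and miR-29 from 0.0127% to 0.00556%, which follows from the genes removed. With both strands together 9 lists moved, leukocyte genes most, from 0.0502% to 0.109%. With 1 value per locus, the miR-200 list went from percentile 99.9 to 92.3 and let-7 from 98.1 to 96.6 among random lists, inside the central 95%; the other 20 lists run kept their side.

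The count minimum also mattered. With at least 1 count in both libraries, 611 genes were detected, Spearman's rho was 0.967, the median absolute log2 difference 0.29 and 98 genes differed over 2-fold. With at least 50 counts, rho was 0.997, the median difference 0.12, the coefficient of variation 0.106 and 2 genes differed over 2-fold. Without Mir802 alone, at the main minimum, the coefficient was 0.108. The 10 most abundant genes held 42.2% of the counts with Mir143 left out of both the total and the ranking. They held 53.3% without genes that share sequence. Both values follow from the genes removed.

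Ratios between lists changed side of the planned spread in 3 of 11 cases. Erythroid over leukocyte, at -0.62, exceeded its own gap but not that spread. It was -1.77 with both strands counted, through Mir142b, and ranged from -0.79 to -0.45 in single libraries. Intestinal epithelium over pancreas ranged from 0.35 to 1.11 in single libraries, as Mir375 differed, and was 0.19 without genes that share sequence. Intestinal epithelium over stratified epithelium was 0.21 without genes that share sequence, which removes Mir194-1 and Mir194-2, and ranged from 0.69 to 0.87 in single libraries. With replicate 1 thinned to the total of replicate 2, 343 genes had at least 10 counts in both libraries.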

Other observations

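Of the genes outside the lists, Mir130a and Mir21a fell under the naming rule, and the others were named here after their values were seen. The tests on Mir802, on the epithelial share and on the Hox clusters were chosen only after the results were seen; those on pancreatic genes and on clusters were set beforehand.

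Several abundant microRNAs belonged to none of the lists. Mir130a (28698 ± 169 CPM; chromosome 2, 84741115 to 84741178) and Mir130b (7103 ± 84.3 CPM) share a seed family. Mir21a (17954 ± 2032 CPM) lies in an exon of Vmp1. Mir744 (6797 ± 240 CPM) lies in an intron of Map2k4 and Mir652 (6192 and 6154 CPM in replicates 1 and 2) in an intron of Tmem164. The sensory-cell cluster Mir182 (5799 ± 197 CPM), Mir183 (2558 ± 80.5 CPM) and Mir96 (1395 ± 154 CPM) was present on chromosome 6 (30165918 to 30169737). Mir140, a cartilage-associated microRNA in Wwp2, had 2257 ± 117 CPM, and Mir137, known from neural tissue, had 2042 and 2316 CPM in replicates 1 and 2, far above the leading gene of the neuronal list, Mir132 (239 ± 39.8 CPM). Rodent-specific Mir467e (1161 ± 16.1 CPM) and Mir467d (953 ± 69.3 CPM), in an intron of Sfmbt2, share sequence with many copies, so their levels are uncertain.

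Mir375 and Mir802 stood apart between 2 otherwise similar libraries, and a difference in the tissue dissected is a candidate explanation. Whether a larger epithelial share in replicate 2 was the whole cause for both genes cannot be decided from the size of their differences. They were singled out as the only genes with a mean of at least 50 CPM over 2-fold apart. Every other such gene, the epithelial members included, thus had to lie under 2-fold. The 9 detected members of the intestinal epithelial and miR-200 lists were higher by a median log2 of 0.41 (SD 0.15, range 0.14 to 0.59), well under the 1.20 of Mir375 and the 6.42 of Mir802. For Mir802, the hepatocyte gene Mir122 gained 11.2 CPM (interval 3.39 to 18.9) while Mir802 gained 135 CPM. This would speak against liver tissue only if liver yields at least as many counts of Mir122 as of Mir802. The series holds no liver library to show that, so liver tissue stays open. Pancreatic tissue stays open for Mir375: Mir216a, Mir216b and Mir217 together were higher by 1.06, but 87 and 47 counts left an interval of 0.52 to 1.59 that includes the Mir375 value. Collection day cannot be told apart from replicate, and with 1 group no explanation resting on a difference between conditions was tested.

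The Hox cluster genes were lower in replicate 2, and a larger anterior part of the gut there might account for this. In that case the miR-196 genes, among posterior Hox genes, should fall further below than Mir10a and Mir10b. Mir196b was at -0.39 (interval -0.41 to -0.37), Mir196a-2 at -0.37 (-0.47 to -0.27), Mir10b at -0.33 (-0.34 to -0.33) and Mir10a at -0.15 (-0.16 to -0.14). The order matched, but the interval of Mir196a-2, whose smaller difference was the deciding value (-0.37), overlapped that of Mir10b. Mir10b also lay nearer to the miR-196 genes than to Mir10a, and the intervals cover counting error only. The hypothesis stays open.

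Neighbouring microRNAs moved together between the libraries. Among 108 genes with a mean of at least 100 CPM in 33 groups of neighbours, the SD of the log2 differences within groups was 0.14, against a median of 0.18 when the differences were permuted over these genes. The one-sided permutation p of 0.0005 was the smallest that 2000 permutations can give. Without genes that share sequence it was 0.003 (73 genes, 19 groups), and leaving out each group in turn gave at most 0.004. These values are consistent with common transcription of cluster members as a hypothesis, and the value without genes that share sequence argues against reads split between copies as the whole cause.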
